A study of Mus musculus with 20 samples.

How the data were processed

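The series holds mouse data, labelled female and 12 months old, and 4 of its experiments were analysed. The first 3 bear on 5xFAD mice, which carry human transgenes and build up amyloid in the brain. The sample titles of the fourth name the treatment and no genotype. In the first, Lineage-negative cKit+ progenitors (Sca1-negative and Sca1-positive cells mixed 1:1 after sorting, per the labels' protocols) of femur and tibia marrow, called femur here, and of skull marrow were tagged with multiplexing oligonucleotides and run in 2 lanes of a droplet 3' assay. The groups were femur WT (3 mice, all in lane 1), femur 5xFAD (4 mice, 1 in lane 1 and 3 in lane 2), skull WT (2 pools of mice, 1 per lane) and skull 5xFAD (2 pools, 1 per lane). In the second, CD11b+ CD45+ brain cells of 2 WT and 2 5xFAD mice were run in 1 lane of a probe-based assay. In the third, CD11b+ brain cells of 5xFAD mice rebuilt with IFNAR1-KO marrow (4 mice) or WT marrow (4 mice) were run in 2 lanes of a 3' assay with antibody tags for the CD45.1 and CD45.2 forms of CD45; each lane held 2 mice of each group. In the fourth, femur marrow Ly6C-high monocytes of mice given PBS (3) or poly-IC, a double-stranded RNA mimic that induces type I interferon (4), were sequenced in bulk.

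The deposited progenitor matrices held UMI counts of every barcode, made with Cell Ranger 7.1.0 per the file headers and mm10 per the submitters' processing notes, for 27998 genes; the authors deposited a table with the tag of each called cell and, as a fraction, the probability of that assignment. The deposited brain matrices held UMI counts of called cells of 1 mouse each, for 19070 genes in the probe-based assay and 33696 genes in the chimeras, whose files also held counts of both antibody tags; their Cell Ranger version is not given. The deposited monocyte table, named normalized counts, held log2 values of 10470 genes in the form of a variance-stabilizing transformation: every column shared a lowest value of 11.2564, and inverting that form gave whole multiples of 1 step per sample for 100% of values at a tolerance of 0.01. This differed from the unit planned for. The inverted values were taken as normalized counts and, divided by the step, as recovered reads. The libraries of femur CD11b+ cells came without count matrices and were not analysed here; the barcode lists of the single-mouse matrices and the probe barcode table were not used here.

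Depth after filtering is given with the groups in the results: 370 to 13175 cells and 3512857 to 96511340 UMIs per mouse or pool, and 11926487 to 18195808 recovered reads per monocyte sample. Intervals and floors cover counting error only; a group at 0 was set to a floor of 3 counts over the group, and a group with 1 to 3 counts was given the ratio with its 95% exact binomial interval.

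Cells were kept with at least 1000 UMIs and 500 genes (500 UMIs and 300 genes in the probe-based assay) and at most 10% mitochondrial counts; progenitors also needed an assignment to 1 tag. Scrublet in scanpy 1.11.5 was run per lane or mouse. It called 2102 of 25409 progenitors (8.27%), but 20 of 41158 brain cells (0.0486%) and 14 of 7641 chimera cells (0.183%), too few to have worked in those assays, so removing the highest scores at 0.8% per 1000 cells was added as an alternative. Kept were 23307, 41138 and 7627 cells. Counts were scaled per cell and log-transformed, 2000 variable genes (without members of the interferon, MHC, disease-associated microglia, immediate early and cell cycle lists) and 30 principal components (scikit-learn 1.9.0) fed a graph of 15 neighbours, and Leiden clusters (igraph 0.11.9, resolution 1, seed 1) were named from marker lists written before the data were examined. A cluster took the name of its best-scoring type, among types with at least 3 markers detected in 10% of its cells, if the score reached 0.2. A type scoring at least 0.8 of the best one with more markers among the cluster's 10 genes highest by fold took its place. Clusters stayed unnamed where the top 10 genes held more markers of another type, where an unrelated type also scored 0.5, or under a further rule for low UMIs. These thresholds were set after the clusters were seen. Unnamed clusters held 10.7% of femur 5xFAD and 11.5% of femur WT cells, 4.76% of skull 5xFAD and 7.69% of skull WT cells, 12.6% of brain 5xFAD and 24.0% of brain WT cells, and 31.7% of IFNAR1-KO and 26.0% of WT donor chimera cells.

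Raw counts were summed per mouse or pool, over all kept progenitors or over a cell class with at least 20 cells per sample. Genes passed edgeR's filterByExpr. edgeR 4.0.16 quasi-likelihood F tests (two-sided) used TMM factors and a lane term where a comparison spanned 2 lanes; Benjamini-Hochberg adjusted p under 0.05 made a call. All 11 progenitor sub-samples shared 1 fit for the femur, skull, skull against femur and genotype by bone contrasts. In the chimeras, macrophages were the border-associated and monocyte-like classes together. The planned mixture of the CD45.1 to CD45.2 ratio per lane gave no gene comparison, because in lane 2 every called cell fell in its higher component; cells were instead called at a 3-fold ratio with at least 10 tag UMIs, compared within mouse. Monocytes were fitted with limma 3.58.1 (trend) on log2 of the normalized count plus 1 for genes with a mean of at least 10. Shares of cells were compared by two-sided exact permutation tests over all splits, adjusted over classes. R 4.3.3, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 were used, with matplotlib 3.10.9 for plots.

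Gene lists, 24 for pathways and states and 12 for other cell types, were written before the data were examined and tested with limma's camera (two-sided, preset correlation 0.01) when at least 5 members were measured, on log2 CPM with a prior count of 2 or on the monocyte log2 values. Beside it stand camera with an estimated correlation, which lets the members move together, and fry, which asks whether a list moves as a whole; both were adjusted over the lists of a comparison. Every list call named below was lost with an estimated correlation except those of the 4 chimera classes fitted alone. A further list took the genes higher in poly-IC monocytes with adjusted p under 0.05 and a log2 fold change of at least 1, at most 100; 7 genes met it. Named genes followed a rule fixed before the data were examined: the 8 genes per direction with the largest fold among calls with a mean of at least 20 CPM over the samples (50 normalized counts in monocytes), leaving out predicted, mitochondrial and receptor segment genes, the 3 members with the smallest p of each pathway list called by camera and of the type I interferon list everywhere, and Ifnar1, Ifnar2, Apoe, Trem2 and Ptprc; a gene outside it is said to be chosen after its values were seen. Some genes that met the rule are not reported here; they stayed in the lists and counts, and were left out of the search for single samples far from their group.

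Each gene comparison was tested on simulated data with counts drawn at the real depth and spread, 100 genes changed 2-fold and 100 changed 4-fold. At 2-fold and 4-fold it recovered 73% and 95% in brain microglia, 78% and 92% in chimera microglia, 71% and 99% in chimera macrophages, 66% and 89% for skull against femur, 42% and 76% in femur, 36% and 73% in skull, 16% and 64% for the interaction, 25% and 60% in monocytes and 2% and 59% for CD45.1 against CD45.2; 2.44% to 10.2% of calls were genes left unchanged.

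Alternatives changed 1 choice at a time: DESeq2 1.42.0, its size factors, no gene filter or at least 10 CPM in as many samples as the smaller group, a stricter cell filter (2000 UMIs, or 1000 in the probe-based assay, and 5% mitochondrial), Scrublet calls kept, Leiden resolutions 0.5 and 2, other cell classes, no lane term, lane 1 alone, an assignment probability of at least 0.99, other pseudocounts and scalings in monocytes, blocks by sample number, and leaving out each sample. A count of genes was taken as alike within 1.5-fold; a direction counted as reversed only where the reported value or the alternative was called. Other splits of the samples were fitted, all of them up to 100 and otherwise 100 drawn. Same-group samples were checked for shared reads.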

Results

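Gene expression was measured in marrow progenitors, brain myeloid cells and marrow monocytes of mice labelled female and 12 months old, to ask how amyloid disease (the 5xFAD transgenes) and type I interferon signalling change them. Progenitors came from the femur of 4 5xFAD mice (1824 to 5138 kept cells and 15653672 to 44437320 UMIs per mouse) and 3 WT mice (776 to 4090 cells, 4360077 to 40387423 UMIs). Skull progenitors came from 2 5xFAD pools (370 to 1283 cells, 3512857 to 9361687 UMIs) and 2 WT pools (929 to 984 cells, 6659840 to 7647749 UMIs). Brain myeloid cells came from 2 5xFAD mice (11015 to 13175 cells, 77936232 to 96511340 UMIs) and 2 WT mice (7530 to 9418 cells, 39001622 to 54268789 UMIs). Chimeras, 5xFAD mice whose marrow was replaced, had received IFNAR1-KO marrow, which lacks a chain of the type I interferon receptor (4 mice, 709 to 1176 cells, 10273514 to 28907023 UMIs), or WT marrow (4 mice, 533 to 1251 cells, 12195855 to 29916307 UMIs). Ly6C-high monocytes came from 3 mice given PBS and 4 given poly-IC, with 11926487 to 18195808 recovered reads each. Values below are CPM from summed counts, as mean ± SD over mice or pools, and monocyte values are normalized counts.

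Microglia of 5xFAD mice switched on the disease-associated program. Apoe, a lipid carrier and the main genetic risk factor for late Alzheimer's disease, rose 13.9-fold (10240 against 738 CPM, adjusted p = 0.00239 in edgeR, n = 2 per group). Cst7, which encodes the protease inhibitor cystatin F, rose 49.8-fold (1195 ± 153 against 24.1 ± 6.25 CPM, adjusted p = 0.00126), and Axl, a receptor that takes up dying cells, rose 10.1-fold (adjusted p = 0.000554). The surface protein Gpnmb rose 126-fold from 1.42 ± 1.31 CPM and the heparanase gene Hpse 80.8-fold. P2ry12, the purine receptor of resting microglia, fell to 0.615-fold (1493 against 2427 CPM, adjusted p = 0.00494). Trem2, the lipid receptor that drives this program, rose 1.79-fold (adjusted p = 0.00593).

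Among 11629 genes, 2175 passed, 1365 higher and 810 lower in 5xFAD microglia; leaving 1 mouse out gave 909 to 1337 and a replicate block 1362. Beyond Gpnmb, Hpse and Cst7 the largest rises by the named-gene rule were those of Pianp (69.97-fold), the collagen crosslinker Lox (33.0-fold), the vesicle gene Rab7b (22.7-fold), the fatty acid carrier Fabp5 (18.9-fold) and the B cell chemokine Cxcl13 (16.9-fold). The steepest falls were in the adhesion gene Ceacam1 (0.151-fold), Gpr165 (0.231-fold), the transcription factor Hlf (0.310-fold), Sema4b (0.322-fold), Tmem44 (0.372-fold), Mdfi (0.388-fold), Myo18b (0.394-fold) and Cass4 (0.408-fold). The disease-associated list rose as a group: 36 of its 38 measured members passed upward and 37 did so adjusted over the list alone, among them Lilrb4a (9.56-fold) and Csf1 (5.78-fold). Camera gave the list an adjusted p of 1.33e-21, against an adjusted p = 0.206 with an estimated correlation.

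Interferon-induced genes rose with it. Ifitm3, which blocks virus entry, rose 4.93-fold (adjusted p = 0.00119), the DNA sensor family gene Ifi207 rose 6.42-fold and the Schlafen gene Slfn5 rose 4.37-fold. Of 48 measured type I interferon genes, 42 passed upward, 0 downward and 6 did not pass, with 45 up adjusted over the list alone (camera adjusted p = 3.27e-19, adjusted p = 0.399 with an estimated correlation). Of 18 type II genes 9 rose and 1 fell (11 and 1 over the list alone, camera adjusted p = 0.00104), led by the T cell chemokines Cxcl10 (7.46-fold) and Cxcl9 (8.19-fold) and the GTPase Tgtp1 (5.06-fold). MHC class I presentation followed with 12 of 15 members up (14 over the list alone, camera adjusted p = 2.65e-07), including H2-D1 (3.36-fold), H2-K1 (2.59-fold) and H2-Q6 (3.74-fold). Of MHC class II genes 4 of 10 members passed upward (4 over the list alone, camera adjusted p = 0.029), as in H2-Ob (1.53-fold), H2-Oa (1.39-fold) and the cathepsin Ctss (1.31-fold). The receptor genes themselves moved little: Ifnar1 was at 0.975-fold (adjusted p = 0.72), and Ifnar2 rose 1.28-fold (adjusted p = 0.0161). Ptprc, which encodes CD45, rose 1.36-fold (adjusted p = 0.0456).

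**Figure D1:**
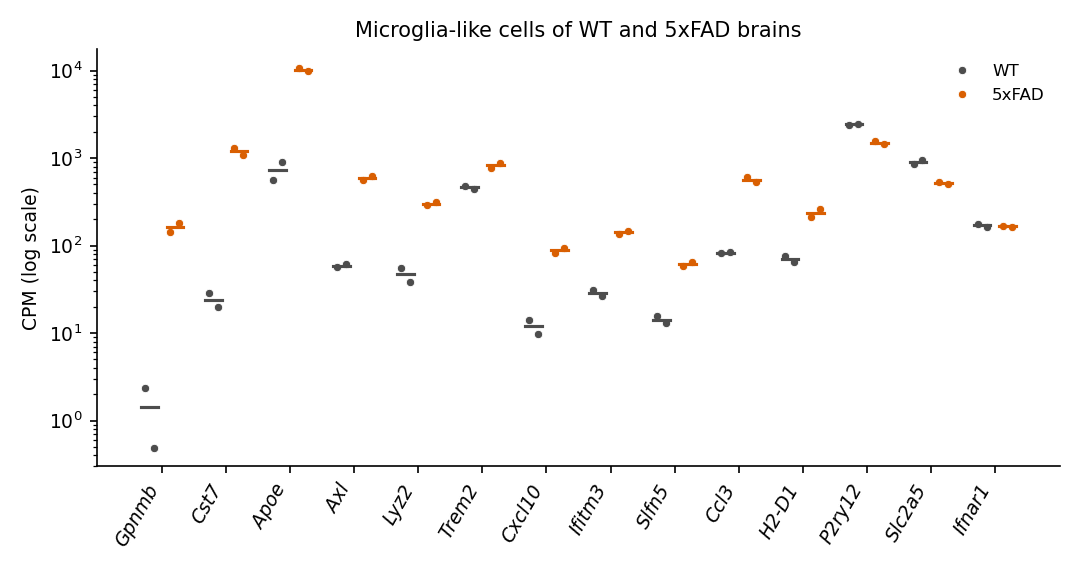
Summed CPM of named genes in microglia-like cells of 2 WT and 2 5xFAD brains on a log axis; horizontal bars are group means and points are mice. Apoe stood at 10240 against 738 CPM and Cst7 at 1195 against 24.1 CPM, while P2ry12 stood at 1493 against 2427 CPM.

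Inflammatory, metabolic and clearance programs changed in the same cells. The macrophage chemokines Ccl3 (6.85-fold), Ccl4 (6.07-fold) and Ccl2 (2.83-fold) led the inflammatory list, in which 10 of 23 members rose (11 over the list alone, camera adjusted p = 1.75e-05). Hypoxia and glycolysis genes rose in 13 of 17 cases (14; 5.41e-08), led by the oxygen-sensing hydroxylase Egln3 (29.9-fold), Mif (3.03-fold) and Gpi1 (1.6-fold). Respiratory chain genes rose in 23 of 33 (28; 3.83e-10), with Cox6a1 at 2.06-fold, Cox8a at 1.67-fold and Cox6b1 at 1.52-fold. Cholesterol synthesis rose in 15 of 18 (16; 6.08e-09), as in Insig1 (2.4-fold) and Dhcr7 (1.62-fold). Lysosome and phagocytosis genes rose in 21 of 34 (25; 5.97e-09), among them the cholesterol exporter Npc2 (2.34-fold) and the scavenger receptor Msr1 (5.91-fold). Homeostatic genes fell in 11 of 22 cases (16; 8.77e-08), with Slc2a5 at 0.583-fold and Ecscr at 0.607-fold. Immediate early genes rose in 12 of 23 cases and fell in 1 (14 and 2; 0.00069), with Egr1 at 1.82-fold, Egr2 at 4.82-fold and Atf3 at 2.98-fold. These parentheses give the count adjusted over the list alone and camera's adjusted p. Monocyte differentiation (5 of 18, 8 up and 1 down; 0.0332), with Lyz2 at 6.44-fold and Fn1 at 3.68-fold, and the list of infiltrating macrophages (4 of 17, 7; 0.00552), with Cybb at 6.79-fold and Cd44 at 2.62-fold, rose as well. Fn1, Cybb and Cd44 lay lower in 5xFAD when all brain cells were summed (log2 fold changes of -0.36, -0.0597 and -0.28). The adjusted p was 0.399 with an estimated correlation for each of these lists except MHC class II (0.484). Different clusters held the microglia of the groups: clusters 6 and 9 held 12.8% and 18.8% of the 5xFAD microglia against 1.36% and 1.28% in WT, and clusters 0 and 4 held 7.58% and 3.58% against 31.2% and 23.3%.

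Other brain classes had few genes called. Border-associated macrophages had 7 calls in edgeR, 6 up and 1 down (DESeq2 16), with Pianp (17.9-fold), Cst7 (9.23-fold), Gpnmb (4.38-fold) and Ctsl (1.73-fold) among those up. Pianp, Cst7 and Gpnmb rose more in microglia, and transcripts carried over from microglia were not excluded. The NK and innate lymphoid class, a cluster that scored 1 for NK and 0.978 for T cell markers and so mixes both, had 6 calls, all up (DESeq2 3), among them the interferon-induced Ifit3 (14.6-fold) and Usp18, the chemokine Ccl12 (20.8-fold) and the T cell genes Cd8a (12.3-fold) and Trac (7.93-fold). A change in the share of T cells within it was not separated. Its type I interferon list had a median log2 fold change of 1.23 (camera adjusted p = 9.18e-28, adjusted p = 0.219 with an estimated correlation). The edgeR fits called 0 genes in dendritic cells (713 at an unadjusted p under 0.05, DESeq2 16), monocytes (288, DESeq2 11) and neutrophils (337, DESeq2 10). Camera still called the type I interferon list higher in dendritic cells (median 0.15, adjusted p = 0.00141), monocytes (median 0.32, adjusted p = 1.22e-06) and neutrophils (median 0.39, adjusted p = 0.000905), each with an adjusted p = 0.6254 with an estimated correlation, and not in border-associated macrophages (0.871). These class genes were chosen after their values were seen. Microglia made up 75.5 ± 0.864% of kept cells in 5xFAD and 60.6 ± 6.69% in WT brains (difference 14.9 points), and unnamed clusters 12.6% and 24.0%. With 2 mice per group the two-sided exact permutation test cannot go below p = 0.333, its value for microglia here.

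In bone marrow progenitors of the femur, no single gene passed the test between 5xFAD and WT mice over all cells, although Ftl1, described with the cell classes, lay higher in every 5xFAD femur. The lactate enzyme gene Ldha, the interferon-induced exonuclease Isg20 and the neutrophil peroxidase Mpo stood among the named genes, and none passed. Isg20 lay at a log2 fold change of 0.48 ± 0.20 (SE; 39.7 ± 4.72 CPM in 4 5xFAD against 27.5 ± 5.72 in 3 WT mice, adjusted p = 0.9999 in edgeR). Ifnar1 lay at -0.17 ± 0.12 (19.8 ± 0.727 against 21.9 ± 2.87 CPM). Of 13825 genes tested in edgeR, 0 passed and 250 had an unadjusted p under 0.05, DESeq2 called 1. Of the 4 femur 5xFAD mice 3 were in lane 2, and every femur WT mouse was in lane 1, so the lane term rests on that mouse and the skull pools.

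Lists moved where single genes did not. Primary granule genes lay higher in 5xFAD femur (camera adjusted p = 0.00111, adjusted p = 0.949 with an estimated correlation), with Mpo at 0.91, Ctsg at 0.99 and Gstm1 at 0.67. These fitted values carry the lane term: plain means ran the other way, at 2151 ± 615 against 2468 ± 682 CPM for Mpo and 1699 against 1901 for Ctsg. That term rests largely on the skull pools, where granulocyte progenitors made up 2.16% and 1.18% in lane 2 against 10.2% and 7.93% in lane 1, so the rise was not separated from which skull cells were assigned. Secondary granule genes of ripening neutrophils lay lower (median -2.79, camera adjusted p = 0.00158), with lactoferrin (Ltf) at -4.92 ± 2.55 (20.2 against 148 CPM) and Lcn2 at -3.31 ± 2.04 (62.6 against 335 CPM). These genes go with mature neutrophils left among the progenitors, which made up 7.60% of femur WT 3 and 3.91% of femur 5xFAD 4 against 0.147% to 1.09% in the other femurs, so a progenitor change is not shown. Erythroid genes (0.00807), among them Car1 at 0.84 ± 0.55 (709.7 against 369.7 CPM), respiratory chain genes (0.00158, Uqcrq at 0.31), glycolysis (0.00158, Pgam1 at 0.65) and MHC class I presentation (0.00472, Psmb10 at 0.32) lay higher. The neutrophil (0.00886) and B cell (0.0449) marker lists lay lower and the T and NK list higher (0.0301). With an estimated correlation the adjusted p of each of these lists was 0.949, and 0 members passed adjusted over the list alone. The list of 42 measured type I interferon genes was not called (camera adjusted p = 0.533; median -0.01, mean 0.01, test upward), but it was called higher without femur WT mouse 3 (9.98e-05) or femur 5xFAD mouse 1 (0.0296).

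Within femur cell classes, edgeR made 11 calls over 7 classes, and Ftl1, the ferritin light chain gene, took 6 of them; leaving 1 mouse out gave 4 to 86 calls, and 16 of 35 splits of the mice gave as many. It lay 15.8-fold higher in the granulocyte class (adjusted p = 2.93e-05) and between 14.6-fold and 23.7-fold higher in the other 5 classes where it passed. The remaining calls were Rpl29 (13.8-fold) and the eosinophil peroxidase Epx (18.1-fold) in basophil and mast cell progenitors, Camp (log2 fold change -2.21) and Hddc3 (-2.33) in granulocyte progenitors, and Mroh2a (5.43-fold) in lymphoid progenitors. The fitted values come with the lane term. Plain means were 558 against 65.2 CPM for Rpl29, 50.3 against 5.12 for Epx (3 5xFAD and 2 WT mice) and 15.4 against 5.65 for Mroh2a, each a smaller ratio than the fitted one. Over all cells Rpl29 stood at 837 and 716 CPM in femur 5xFAD 1 and 2, but at 73.2 and 69.6 CPM in 5xFAD 3 and 4, near the 59.3 to 66.5 CPM of WT, so it did not go with genotype. Of the falls, the plain means of Camp ran the other way (230.3 against 204.8 CPM) and those of Hddc3 were alike (13.52 against 13.61 CPM). Over all cells Ftl1 split the mice: 497 to 942 CPM in the 4 5xFAD femurs, 31.5 to 44.5 CPM in the 3 WT femurs, 722 and 51.2 CPM in the 5xFAD skull pools and 562 and 326 CPM in the WT skull pools. Its pseudogene copy Gm10116 ran the other way, at 29.2 to 522 CPM in the 5xFAD femurs and 943 to 1083 CPM in the WT femurs. The sum of Ftl1 and its copies stood at 0.9497-fold, so a rise of ferritin light chain transcripts is not shown. The erythroid class had 0 calls (262 at an unadjusted p under 0.05, DESeq2 1). The lymphoid class had a higher type I interferon list (camera adjusted p = 0.000464, adjusted p = 0.997 with an estimated correlation). No share of a progenitor class passed its test: HSC and multipotent progenitors made up 23.5 ± 11.9% in 5xFAD and 25.0 ± 10.9% in WT femurs, and lymphoid progenitors 20.5 ± 2.18% and 16.3 ± 3.66% (two-sided exact permutation p = 0.2, the smallest over the classes, adjusted p = 0.857). Within lane 1 the 5xFAD mouse held 13.8% and 19.5%. The femurs fell apart by HSC share across genotypes: 27.8% to 34.3% in 5xFAD 2 and 3 and WT 2 and 3, and 12.6% to 13.8% in 5xFAD 1 and 4 and WT 1.

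Skull progenitors of 5xFAD mice had no single gene past the threshold either. The interferon-induced tether Bst2 lay at a log2 fold change of -0.43 ± 0.27 (77.1 against 104 CPM, 2 pools each, adjusted p = 0.9998 in edgeR) and the antiviral Oas1a at -0.87 ± 0.42. The neutrophil gene Retnlg lay at -5.59 ± 2.26 (3.37 against 124 CPM). edgeR called 0 genes, with 222 at an unadjusted p under 0.05, and DESeq2 called 0. The type I interferon list lay lower (median -0.28, camera adjusted p = 0.00233, adjusted p = 0.756 with an estimated correlation), and without 5xFAD pool 2 its direction turned (adjusted p = 0.994). Type II genes (0.00559, Irgm2 at -1.10), secondary granule genes (1.32e-06, median -2.18), neutrophil markers (4.14e-05), monocyte differentiation (0.00174, Ccr2 at -0.66 and Fn1 at -2.19), basophil markers (0.00174) and homeostatic genes (0.0357, P2ry12 at -0.86) lay lower. Respiratory chain (0.00827, Ndufa5 at 0.17), ribosomal (0.0145, Rplp0 at 0.24) and megakaryocyte genes (0.0464, Pf4 at 0.82) lay higher. Each had an adjusted p of 0.756 with an estimated correlation. Mmp9 had 2 counts in the 5xFAD pools against 86 in WT, a ratio of 0.0258 (95% interval 0.00308 to 0.0962). Mean shares were 33.3% and 26.7% for erythroid and 27.0% and 30.3% for lymphoid progenitors, and 2 pools against 2 were not tested. Mature neutrophils made up 0.0779% and 0.27% of the 5xFAD and 1.12% and 2.26% of the WT pools, and the lower Retnlg, Mmp9, secondary granule and neutrophil lists were not separated from this.

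The difference between the genotype effects of skull and femur was tested directly. edgeR called 0 genes for it (164 at an unadjusted p under 0.05, DESeq2 1). The type I interferon list was lower in skull than in femur relative to WT (median -0.31, camera adjusted p = 0.0114, adjusted p = 0.95 with an estimated correlation), with Bst2 at -0.79 ± 0.37, Eif2ak2 at -0.37 and Oas1a at -1.12, each with an adjusted p of 1 in edgeR. Without skull 5xFAD pool 2 the direction of the list turned (adjusted p = 0.749). MHC class I presentation (0.00321, Psmb10 at -0.45), monocyte differentiation (0.00321, F13a1 at -1.20 and Ccl9 at -0.96), basophil markers (0.00855) and lysosome genes (0.0312, Tyrobp at -0.93) were lower too, each with an adjusted p of 0.95 with an estimated correlation.

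More genes were called between skull and femur progenitors than between 5xFAD and WT progenitors, but the count fell to 0 without skull WT pool 2. The bone contrast also recovered more simulated 2-fold changes, 66% against 42% for genotype in femur. Stress and activation genes were higher in skull: Junb, a growth-response transcription factor, rose 2.32-fold (235 ± 26.0 CPM in 4 pools against 101 ± 17.4 in 7 mice, adjusted p = 0.00738 in edgeR). The lymphoid surrogate light chain genes Vpreb1 (2.32-fold, 424 against 181 CPM, adjusted p = 0.0248) and Igll1 (2.21-fold) and the antigen receptor polymerase Dntt (1.53-fold) rose. Lymphoid progenitors made up 27.0% to 32.6% of the skull pools and 13.2% to 23.7% of the femurs, so this rise was not separated from cell shares. Myeloid genes were lower: the clotting factor gene F13a1 fell to 0.417-fold (105 against 235 CPM, adjusted p = 0.0494), the chemokine Ccl9 to 0.473-fold and the interleukin-6 receptor Il6ra to 0.5677-fold. In all 156 genes passed, 95 higher and 61 lower in skull. Others were Id3 (2.74-fold), Skil (2.5-fold), Egr1 (2.47-fold), Nr4a2 (2.35-fold), Dusp1 (2.34-fold) and Nr4a1 (2.25-fold) upward, and Emb (0.384-fold), Plppr3 (0.452-fold), Parp8 (0.497-fold), Serpinf1 (0.499-fold) and Fndc3b (0.508-fold) downward.

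Immediate early genes rose in 12 of 22 cases (17 adjusted over the list alone, camera adjusted p = 1.96e-13, fry 0.042), with Btg2 at 2.16-fold and Egr2 at 5.93-fold, and inflammatory genes in 4 of 21 (6; 0.0135, fry 0.042), with Nfkbia at 1.88-fold, Tnfaip3 at 3.11-fold and Cxcl2 at 7.2-fold. Such genes also respond to cell isolation, and by the sample descriptions the skull bones were ground in a mortar while the long bones were flushed with a syringe. Lymphoid priming rose in 3 of 17 (8 up and 3 down over the list alone; 0.0091), and monocyte differentiation fell in 2 of 20 (10; 1.04e-05), with Csf1r just short of passing (0.45-fold, adjusted p = 0.052). Primary granule genes fell as a list (1.31e-07) although 0 of 13 members passed over all genes and 12 did over the list alone, as in Mpo (0.425-fold, adjusted p = 0.0611), Gstm1 and Plac8. Erythroid genes rose (7.6e-07; 0 and 10 of 21), and so did G2 and M phase genes (2.64e-08; 0 and 10 of 22), as in Ckap2l, and S phase genes (0.0189), as in Slbp, of which none passed. Glycolysis fell in 1 of 19 (9; 5.72e-05), Pkm at 0.592-fold. The lysosome list was lower by camera (0.019), yet 2 of its 33 members, C1qb (5.87-fold) and C1qa (4.74-fold), passed upward and 0 downward (4 up and 11 down over the list alone). Infiltrating macrophage genes were lower (0.00755) with 1 member up, Itga4 (1.27-fold). Megakaryocyte (0.0149), MHC class II (0.0404; Cd74 at 2.88-fold, adjusted p = 0.0764), B cell (0.00544), erythroid cell (0.0091) and platelet (0.0469) lists were higher, and secondary granule (0.0169) and neutrophil (0.0469) lists lower. With an estimated correlation the adjusted p of these lists lay between 0.66 and 0.687. Type I interferon genes did not differ (0.629). The count fell to 0 without skull WT pool 2 and rose to 752 without femur 5xFAD mouse 1, so it rests on single samples. It also fell to 0 without both lane 2 skull pools, in which granulocyte progenitors made up 2.16% and 1.18% of cells against 10.2% and 7.93% in the lane 1 pools, and erythroid progenitors 44.3% and 34.6% against 22.4% and 18.9%. In lane 2, 5746 cells with a skull pool's tag highest were left unassigned, with granulocyte markers 4.01-fold those of assigned skull cells. Assigned femur cells of lane 2 held a similar level (9577 against 10728 CPM in the unassigned cells). The ratio therefore does not show these to be skull cells. Lower myeloid and higher erythroid genes in skull were not separated from which cells were assigned.

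Interferon-induced genes were lower in donor-type macrophages of 5xFAD brains rebuilt with IFNAR1-KO marrow than in those rebuilt with WT marrow. But the donor groups also differed in Y-linked transcripts. Donor-type names classes picked by cluster, not by a donor mark, and the CD45 form of the donors is not given. In WT donor chimera 2, 42 monocyte-like cells were called CD45.1, the tag of most of its called microglia, and 154 CD45.2. The counts were 16 and 29 in WT donor chimera 3, but 1 and 106 in WT donor chimera 4 and 0 and 117 in WT donor chimera 1. Of neutrophils in WT donor chimera 2, 46 were called CD45.1 and 91 CD45.2. Ifi27l2a fell to 0.0412-fold (24.0 ± 15.9 CPM in 4 IFNAR1-KO against 550 ± 182 in 4 WT donor chimeras, adjusted p = 0.000145 in edgeR). Slfn5 fell to 0.0735-fold (17.3 against 224 CPM), the antiviral Oasl2 to 0.0686-fold (adjusted p = 5.11e-05), the ubiquitin-like modifier Isg15 to 0.112-fold and Irf7, the transcription factor that amplifies the response, to 0.163-fold (adjusted p = 8.39e-05). The antigen-presenting genes H2-Ab1 (2.04-fold), H2-Aa (2.04-fold, 3439 against 1685 CPM) and H2-Eb1 (2.2-fold) rose, each with an adjusted p of 0.00343. The summed macrophages held more border-associated and fewer monocyte-like cells in the IFNAR1-KO group (3.87% against 2.35% and 5.95% against 12.5% of kept cells), and in monocytes alone the 4 genes called higher were Y-linked (Eif2s3y, Uty, Ddx3y and Kdm5d), so the other rises were not separated from that mix.

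Of 9816 genes, 244 passed, 167 higher and 77 lower; leaving 1 chimera out gave 89 to 474, a stricter cell filter 47 and a Leiden resolution of 2 gave 46. Further falls were those of Ifi213 (0.0658-fold), Ifit2 (0.108-fold) and Xaf1 (0.183-fold). Further rises were the growth factor Igf1 (4.15-fold, 44.1 ± 11.6 against 10.9 ± 7.87 CPM, adjusted p = 0.0179), Plau (4.11-fold), Ctnnd2 (3.98-fold), P3h2 (3.77-fold) and Prkg1 (3.4-fold), and 3 Y-linked genes, Ddx3y (105-fold), Uty (282 counts against 1, ratio 603, 95% interval 107 to 23885) and Eif2s3y (374 against 2, ratio 400, interval 110 to 3312), although all mice are labelled female. The type I interferon list fell: 38 of 46 members passed downward, 0 upward and 8 did not pass (43 down adjusted over the list alone, camera adjusted p = 9.18e-56, adjusted p = 0.12 with an estimated correlation). MHC class II rose in 4 of 9 (7; 9.69e-08; 0.291 estimated) and homeostatic genes in 5 of 20 (9 up and 1 down; 0.000101; 0.508 estimated), as in Cx3cr1 (1.59-fold), Tgfbr1 (1.61-fold) and Gpr34 (2.11-fold). Lysosome genes rose in 4 of 34 (6; 0.00278; 0.516 estimated), with C1qb (2.05-fold), C1qc (2.06-fold) and Cd63 (2.51-fold), and the erythroid list in 2 of 5 (3 up and 1 down; 0.0126; 0.291 estimated) through Apoe (1.85-fold, adjusted p = 0.00919) and Blvrb (1.69-fold). Cholesterol synthesis rose (0.000167) with 0 members passing. Lists that fell were G2 and M phase (4.95e-08; 0 and 9 of 22; Cdc20 0.663-fold, adjusted p = 0.0511), S phase (0.000583), respiratory chain (7.61e-10, Ndufb7), glycolysis (0.000674, Pkm), ribosomal (1.1e-05, Rps2), primary granule (9.05e-06; 1 of 10, Plac8 at 0.366-fold) and secondary granule genes (0.00961, Wfdc21, which stood at 112.5 CPM in WT donor chimera 2 and at 2.17 to 10.3 in the others of that group); with an estimated correlation their adjusted p lay between 0.291 and 0.516. The disease-associated list had 4 members up of 35 and was not called (0.488).

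The interferon list fell in each donor-type class fitted alone, and there the fall held with an estimated correlation. The median log2 fold change was -1.66 in dendritic cells (22 of 36 members down), -1.55 in monocytes (33 of 43) and -1.04 in neutrophils (10 of 26), each with 4 mice per group and an adjusted p of 0.000831 with an estimated correlation. It was -2.19 in an unnamed macrophage cluster (31 of 35; 0.00576; 3 mice each). These classes had 38, 50, 41 and 121 genes called. Border-associated macrophages were not fitted alone, because only 1 WT donor chimera held at least 20 such cells.

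In microglia of the same chimeras the type I interferon list was not called, and the difference from macrophages was not tested. Their 49 measured type I interferon genes lay at a median log2 fold change of -0.10 (camera adjusted p = 0.355), with Ifi206 at 0.81, Samd9l at 0.73 and Ifi213 at 0.92, each with an adjusted p of 1 in edgeR. The early response gene Dusp1 lay at 0.675-fold (81.9 ± 8.04 against 122 ± 16.7 CPM, 4 mice each) and the cathepsin gene Ctsh at 0.739-fold, both with an adjusted p of 0.805. Of 12140 genes edgeR called 0, with 422 at an unadjusted p under 0.05, and DESeq2 called 9. Lists that lay lower were MHC class I presentation (0.000213, H2-Q7 and H2-D1), immediate early genes (0.00061, Fos; 2 members over the list alone), respiratory chain (0.00061, Atp5a1), ribosomal (6.5e-05, Rplp1) and lysosome genes (0.0266, Mertk); each had an adjusted p of 0.969 with an estimated correlation. The same clusters held the microglia of both groups (cluster 3 held 51.2% and 46.9%). The interferon list was called lower in the IFNAR1-KO group without IFNAR1-KO chimera 2 (0.00452) or 3 (0.000976) or WT donor chimera 1 (0.00144) and at a Leiden resolution of 2 (0.0495). It was also called lower with every cluster whose best type is microglia (1.45e-23) and with all cells summed (3.71e-21). Both sets take in clusters outside the microglia class. All cells include the donor-type classes in which the list fell, at medians from -1.04 to -2.19. Neither set therefore tests microglia alone.

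Ifnar1 transcripts were still counted in the IFNAR1-KO chimeras. Neutrophils held 70.4 ± 30.9 CPM against 54.3 ± 13.1 in WT donor chimeras, and summed macrophages 155 ± 12.0 against 115 ± 15.8 (1.35-fold, adjusted p = 0.121 in edgeR), while an unnamed macrophage cluster held 203 ± 10.1 against 299 ± 29.9 CPM (3 mice each). Microglia held 88.8, 81.9, 88.4 and 80.3 CPM in IFNAR1-KO chimeras 1 to 4 and 82.9, 80.5, 80.5 and 74.1 CPM in WT donor chimeras 1 to 4. The assay reads the 3' end and the deleted part of the gene is not given, so these counts check nothing about the knockout.

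Cell class shares differed between the chimera groups without passing the test. Monocyte-like cells made up 5.95 ± 1.43% against 12.5 ± 3.58% and border-associated macrophages 3.87 ± 0.423% against 2.35 ± 0.523%, without overlap between 4 and 4 mice. Both had a two-sided exact permutation p of 0.0286, the smallest this design can give, and an adjusted p of 0.143, so neither passed. Neutrophils stood at 7.06 ± 3.19% against 13.8 ± 5.84% (exact p = 0.0571) and microglia at 46.2 ± 15.9% against 39.5 ± 9.67%.

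Cells carrying the CD45.1 tag were compared with CD45.2 cells within WT donor chimeras 2, 3 and 4, the mice with at least 20 called cells of both. Microglial identity genes were higher in CD45.1 cells: the transcription factor Sall1 rose 5.81-fold (164 against 29.1 CPM, adjusted p = 0.0477 in edgeR, n = 3 pairs), Adgrg1 5.49-fold and Ecscr 4.8-fold. Ms4a7, a macrophage gene, fell to 0.106-fold and Trim12a to 0.00811-fold. The CD45.1 and CD45.2 cells were largely of different types, and no fit within 1 class was made: 56.3%, 81.3% and 94.0% of CD45.1 cells were microglia-like in these mice, against 3.09%, 5.56% and 0.725% of CD45.2 cells. Of 12519 genes, 398 passed, 362 higher and 36 lower. Others up were Plekhh2 (12.1-fold), Esrrg (11.28-fold), Jam2 (9.69-fold), Plpp1 (9.58-fold), Mrc2 (8.84-fold), Cd34 (7.6-fold), Klf12 (7.02-fold) and Naalad2 (6.95-fold); others down were Ppfia4 (0.194-fold), Trim12c (0.214-fold), Sash1 (0.237-fold), Negr1 (0.278-fold), Psd3 (0.28-fold) and Dhx40 (0.317-fold). With a mixture per mouse as the calling rule, Ms4a7, Negr1 and Psd3 turned upward (log2 fold changes of 0.0445, 0.18 and 0.88). Homeostatic genes rose in 16 of 24 (24 adjusted over the list alone, camera adjusted p = 6.14e-13), disease-associated genes in 3 of 39 with 1 down (17 and 4; 0.0187), as in Dkk2 and Cd9, and lysosome genes in 1 of 34 (24 and 1; 1.67e-05), Ctsl at 5.58-fold. Type I interferon genes lay lower with 0 members passing (2.36e-05), as did type II genes (0.0156), S phase (7.31e-08; 0 and 20 of 21, Mcm6), G2 and M phase (2.36e-05), primary granule (0.000845), secondary granule (0.00595), respiratory chain (9.89e-08; Atp5g1), ribosomal (9.89e-08), immediate early (0.00379; Btg2 at 0.373-fold), infiltrating macrophage (3.05e-05) and neutrophil genes (0.0475). B cell genes lay lower (0.0165), as did lymphoid priming (0.0153); Ebf1 had 2 counts against 190 (ratio 0.0144, 95% interval 0.00173 to 0.0527) and Cd79a 2 against 128 (0.0214, 0.00256 to 0.0787). With an estimated correlation each of these had an adjusted p of 0.731, except the secondary granule, neutrophil and disease-associated lists (0.748). The count fell to 0 without mouse 2 or mouse 3. CD45.1 cells made up 0.281 ± 0.38% of called cells in IFNAR1-KO and 35.2 ± 26.8% in WT donor chimeras (two-sided exact permutation p = 0.0857, 4 mice each). The tag ratio rule left most microglia of IFNAR1-KO chimeras 1, 2 and 4 uncalled. It called 39 of 244, 20 of 452 and 28 of 524 of them CD45.2, and 2, 0 and 2 CD45.1. In IFNAR1-KO chimera 3 it called 550 of 561 CD45.2, and 410 of 431 in WT donor chimera 1. In WT donor chimeras 2 to 4 it called 216 of 336, 183 of 267 and 187 of 343 CD45.1. The shares of the groups thus rest on different parts of their microglia. The CD45.1 shares also depend on the calling rule. A mixture per mouse gave 34.7 ± 35.1% and 54.9 ± 32.7% (exact permutation p = 0.314), and the planned mixture per lane a difference of -5.46 points (exact permutation p = 0.657). A mixture calls the component of the higher ratio CD45.1. Per mouse its mean log2 ratio was -1.48, -0.88, -0.67 and -0.80 in IFNAR1-KO chimeras 1 to 4 and -0.63 in WT donor chimera 1. It was 1.02, 1.46 and 0.82 in WT donor chimeras 2, 3 and 4. Where it was negative, the cells so called held more CD45.2 than CD45.1 tag on average, which also limits gene results under this rule.

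Y-linked transcripts appeared in donor-type cells of every IFNAR1-KO chimera and hardly in the WT donor chimeras. Summed Y-linked transcripts reached 139 ± 28.9 CPM in neutrophils of 4 IFNAR1-KO chimeras, where between 42.9% and 63.5% of the cells held one, against 0.252 CPM and at most 0.641% of the cells in WT donor chimeras. Monocytes held 195 ± 49.7 against 1.35 CPM. Microglia, which should be of host origin, held 8.63 CPM (0.664% to 4.51% of the cells) against 0.453 CPM, at median depths of 11905 to 16227 UMIs per cell against 8467 to 15538.5 for neutrophils. Xist, the transcript that silences an X chromosome in female cells, stood at 42.2 CPM in IFNAR1-KO and 172 CPM in WT donor neutrophils, and at 1428 and 1338 CPM in microglia. These genes were chosen after their values were seen.

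**Figure D2:**
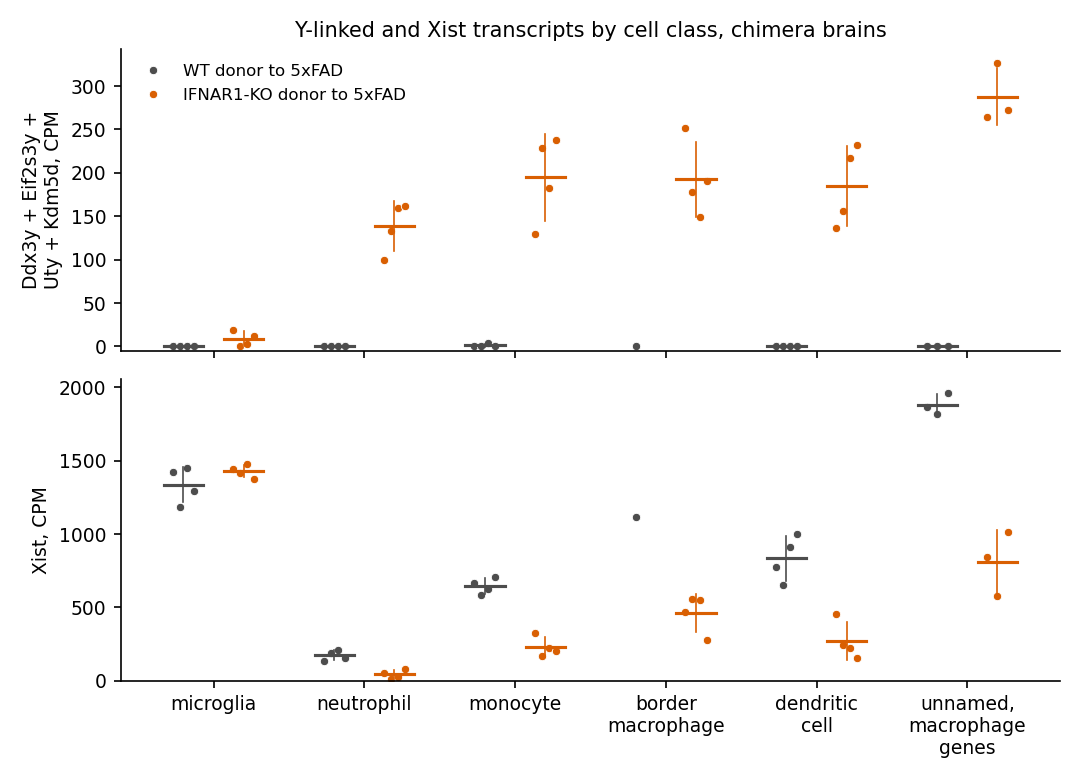
Summed CPM of Y-linked genes and of Xist in 6 cell classes of the chimeras; horizontal bars are group means, whiskers SD and points are mice with at least 20 cells of the class. Y-linked transcripts stood at 139 CPM in neutrophils of the IFNAR1-KO group and at 0.252 CPM in the WT donor group.

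The CD45 tags parted microglia by mouse. The median log2 ratio of the CD45.1 to the CD45.2 tag in microglia was 1.94, 1.93 and 1.69 in WT donor chimeras 2, 3 and 4 and -3.37 in WT donor chimera 1. It was -1.04, -0.89, -3.31 and -0.83 in IFNAR1-KO chimeras 1 to 4, so the groups overlapped. The mean of the other classes lay between -3.84 and -2.80 in every mouse.

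Poly-IC raised interferon-induced genes in marrow monocytes. Ifi44 rose 8.95-fold (1244 ± 313 against 145 ± 65.2 normalized counts, 4 against 3 mice, adjusted p = 0.00164 in limma), Ly6a, the Sca-1 surface protein, 11.02-fold (adjusted p = 0.0383) and Ifi27l2a 2.45-fold (adjusted p = 0.00132). Spp1, which encodes osteopontin, was at 0 in every PBS sample and at 187 ± 123 after poly-IC, at least 190.5-fold higher. Apoe fell to 0.298-fold (547 against 1892, adjusted p = 0.0383) and Fn1, which encodes fibronectin, to 0.614-fold (adjusted p = 0.0166).

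**Figure D3:**
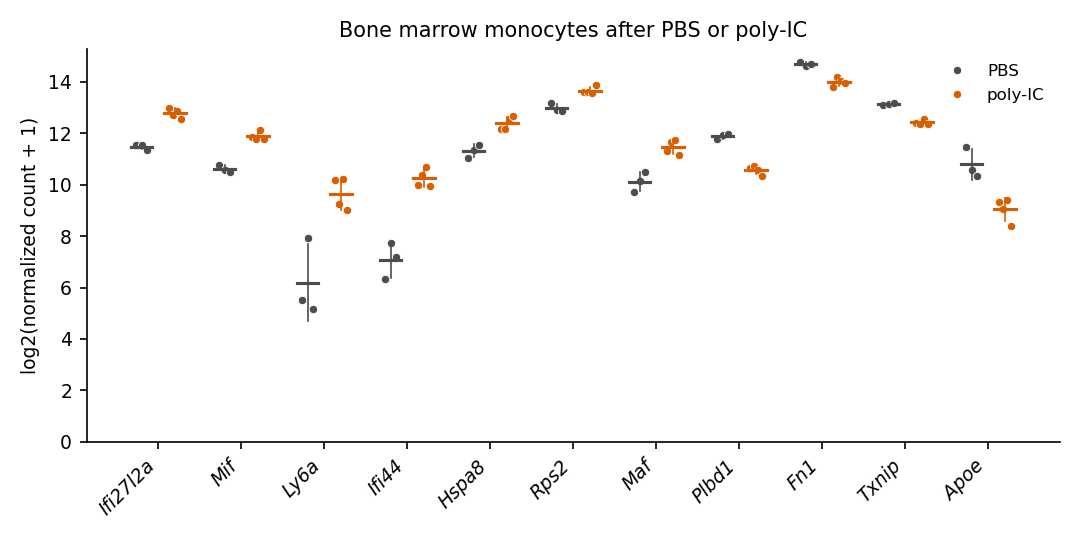
Normalized counts of named genes in Ly6C-high monocytes of 3 PBS and 4 poly-IC mice; horizontal bars are group means, whiskers SD and points are mice. Ifi44 stood at 1244 after poly-IC against 145 after PBS and Apoe at 547 against 1892.

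Of 10455 genes, 14 passed, 9 up and 5 down; leaving 1 sample out gave 4 to 28, and DESeq2 on recovered reads 168. The others were Maf (2.53-fold), Mif (2.42-fold), Hspa8 (2.1-fold), Hsp90ab1 (1.69-fold) and Rps2 (1.6-fold) up and Plbd1 (0.405-fold), AI839979 (0.556-fold) and Txnip (0.61-fold) down. Of 50 type I interferon genes 3 rose and 47 did not pass (17 up and 1 down adjusted over the list alone, camera adjusted p = 1.33e-05, adjusted p = 0.233 with an estimated correlation). MHC class I (0.00222; 3 of 16 over the list alone, H2-T22), S phase (0.00222, Mcm7), G2 and M phase (0.0405, Birc5), respiratory chain (0.00911, Sdhb) and ribosomal genes (0.00233) lay higher. Secondary granule genes (0.00222; 1 up and 10 down over the list alone, Mmp8 at 0.478-fold and adjusted p = 0.0841), monocyte differentiation (0.0222; 1 down, and 2 up and 5 down over the list alone), infiltrating macrophage genes (0.00233), MHC class II (0.0351, H2-Ab1), inflammatory (0.0312, Nlrp3), erythroid (0.0277) and neutrophil lists (0.0176) lay lower. With an estimated correlation no list had an adjusted p under 0.233. The type II list had a positive median and mean but a test pointing down (0.824). The monocyte markers Ly6c2 (1.57-fold, adjusted p = 0.0519) and Cx3cr1 (0.514-fold, adjusted p = 0.115) and Ifnar1 (0.756-fold, adjusted p = 0.673) did not pass.

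The 7 genes raised at least to a log2 fold change of 1 by poly-IC were carried to the other experiments as a list. In 5xFAD microglia 5 of them rose and 1 fell (median 1.60, camera adjusted p = 0.0703, adjusted p = 0.806 with an estimated correlation, fry 0.0226). In femur progenitors the list gave 0.721, in chimera microglia 0.626, in chimera macrophages 0.626 (median 0.41 and a test pointing down) and in CD45.1 cells 0.721.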

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

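Of the tests in this part, those of free RNA, swapped samples, donor sex, tag staining, the Ftl1 variant, genotype and lane, of the interferon list and of the summed macrophages, and the other splits of the monocyte samples, were chosen only after the result was seen.

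Y-linked transcripts stood in donor-type cells of all 4 IFNAR1-KO chimeras, in mice labelled female. Free RNA from a male sample in the same lane would reach every class alike, but microglia held at most 0.191 of the Y-linked level of neutrophils in the same mouse (IFNAR1-KO chimera 1, interval 0.140 to 0.259). A swap between the donor groups would need a WT donor chimera at the level of the IFNAR1-KO group, and 0 were. Male donors in the IFNAR1-KO group alone stay a candidate explanation, and these values go with it. In neutrophils Xist stood at 14.3 to 76.8 CPM in the IFNAR1-KO and 137 to 212 CPM in the WT donor chimeras. Monocytes did not overlap either (167 to 323 against 588 to 709 CPM). The group means lay at least 2.81-fold apart, less than the test asked for, so the test could not decide. The sex of the donors is not given and goes with the donor genotype.

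The CD45.1 to CD45.2 tag ratio of microglia differed between chimeras. Uneven staining as the whole cause would move every class, yet over the 8 mice border-associated macrophages ranged over 0.587 and monocytes over 1.201 log2 units, against 5.32 in microglia, and the mean of the other classes over 1.04, or 0.195 of microglia. Neutrophils ranged over 2.15, dendritic cells over 2.43 and unnamed cells over 3.07, T cells over 2.02 in 3 mice, and NK and innate lymphoid cells over 6.13 between 2 mice with 11 such cells each, so a part played by staining stays open. Microglia replaced by donor cells would carry Y-linked transcripts in IFNAR1-KO chimera 3, where their level was 0.0169 of that of neutrophils; WT donor chimera 1, with a ratio of -3.37, could not be tested this way, so replacement there stays open. Host mice that differ in their Ptprc allele, the gene of CD45, remain a candidate explanation. Among the 100 measured genes nearest Ptprc the microglial level of 16 followed the ratio over the mice, against 498 of 8880 others (5.61%, Fisher's exact p = 0.000161). That test takes genes as independent, although genes can move together over 8 mice. Its p therefore does not measure the spread between mice, and other stretches of the genome were not compared. The host alleles are not given, and no other biological explanation was tested.

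Ftl1 and Rpl29 were high or low by mouse in marrow progenitors. The 5xFAD genotype as the cause would raise both 5xFAD skull pools, but the lowest of them held 0.157 of the Ftl1 level of the lowest WT pool. Lane as the cause would leave mice of lane 1 alike, and the 5xFAD femur there lay 12.0-fold above the highest WT femur. A strain variant against the reference is a candidate explanation, with Ftl1 at least 14.1-fold apart in every class. So are reads shared with pseudogene copies, and the 2 can hold together. Gm10116, the copy measured, ran opposite to Ftl1. It stood at 943 to 1083 CPM in WT femurs, 29.2 and 37.2 CPM in femur 5xFAD 2 and 3, and 522 and 436 CPM in femur 5xFAD 1 and 4. The sum of Ftl1 and its copies stood at 0.9497-fold in femur, so a rise of their total is not shown.

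Other splits of the samples were counted for the femur cell classes and for each comparison over summed cells or monocytes with at least 3 per group. The chimera classes fitted alone were not split. For femur 5xFAD against WT the real split called 0 genes, so 35 of 35 splits reach it by construction and the count decides nothing; 1 split called 81 genes, with femur 5xFAD 2 and 3 beside femur WT 2 and 3, which points to a structure of the samples: HSC and multipotent progenitors made up 27.8% to 34.3% of these 4 femurs and 12.6% to 13.8% of the other 3. For the femur cell classes the real split called 11 genes and 16 of 35 splits as many, so chance cannot be excluded; the highest other called 192, which also points to structure. For skull against femur 1 of 100 splits, the real one, called 156 genes and the highest other 8. No other split drawn reached that count, but it fell to 0 without skull WT pool 2. The splits also cannot part bone from pooling or from how the bones were processed. In chimera microglia the real count was also 0, which 35 of 35 splits reach by construction, so that count decides nothing either; the highest other called 4. In chimera macrophages 1 of 35 splits called as many as the real 244 and the highest other 1. That is a share under 0.05 and the smallest that 35 splits can give. The splits moved mice between lanes, although each lane held 2 mice of each group, so the share takes no account of lane. Fewer splits keep the lanes balanced, and they were not counted apart. The share also cannot part donor genotype from donor sex. For CD45.1 against CD45.2 cells 4 splits are too few for a share under 0.05; the real count was 398, reached by 1 split, and the highest other was 0. For poly-IC 1 of 35 splits reached the real 14 and the highest other called 0, also a share under 0.05 and the smallest that 35 splits can give.

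Single samples far from the rest of their group were looked for in 267 groups of 4 to 10 samples, and 21 (7.87%) held one, where chance alone gives about 1 in 20. Monocyte-like cells made up 3.82% in IFNAR1-KO chimera 3 (others 6.46% to 6.90%). T cells made up 2.80% in WT donor chimera 2 (0.589% to 0.750%). Femur 5xFAD 4 stood out in lymphoid progenitors at 23.7% (19.2% to 19.5%) and in mature neutrophils at 3.91% (0.151% to 0.329%). The same mouse held 11.1 CPM of Cd177 (0.69 to 1.21), 200.3 CPM of Lcn2 (12.4 to 19.5) and 68.9 CPM of Ltf (0.904 to 6.66). These genes belong to the secondary granule list, and which cells held them was not tested. WT donor chimera 2 held 875 CPM of Ctsh in microglia (749 to 768.6) and, in macrophages, 182 CPM of Retnlg (3.04 to 12.1), 1136 CPM of S100a9 (42.2 to 215) and 112.5 CPM of Wfdc21 (2.17 to 10.3). WT donor chimera 1 held 2064 CPM of Rplp1 in microglia (2731 to 2783). Macrophages of WT donor chimera 3 held 1.03 CPM of Eif2s3y (0 to 0.159), 1.03 CPM of Uty (0 in the others) and 34.0 CPM of Rrm1 (89.5 to 92.5). The whole WT donor group held 2 counts of Eif2s3y and 1 of Uty, so these 2 values are within counting noise. IFNAR1-KO chimera 4 held 26.8 CPM of Cyp51 (45.01 to 46.1) and IFNAR1-KO chimera 3 held 65.2 CPM of P3h2 (40.7 to 42.8). Among monocyte samples, poly-IC 4 held 2103 normalized counts of Cx3cr1 (3414 to 3580), 12050 of Rpl6 (at most 10630 in the others) and 14960 of Rps2 (12180 to 12510), and poly-IC 2 held 6771 of Ifnar2 (4380 to 4786).

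Outside the comparisons, 5746 progenitors of lane 2 without an assigned sample had a skull pool's tag as their highest. Few stem and granulocyte progenitors were assigned to the lane 2 skull pools, and whether the missing cells are among these could not be told. Their stem and granulocyte marker levels were at least 1.77-fold those of assigned skull cells (granulocyte markers 4.01-fold). But they also lay near assigned femur cells of lane 2. Granulocyte markers stood at 10728 CPM in the unassigned and 9577 CPM in the femur cells, and stem cell markers at 1589 and 1383 CPM. Unassigned femur cells would give similar ratios. The tags did not assign the 5746 cells, so this stays open.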

How the results depend on the processing

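Of the tests in this part, those without both lane 2 skull pools, with the highest doublet scores removed, with the replicate block outside the monocytes, with the best type per cluster, with the unnamed cluster and with a mixture per mouse were chosen only after the result was seen. So were the settings of the class counts, of the CD45.1 share beside the tag ratio and of the poly-IC list, the list tests of the brain and chimera fits under other settings, and for monocytes DESeq2, edgeR and limma on other scales and the fits without a block. The rest were chosen before the data were examined, and the cause of each change was not tested.

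Over 7033 values of named genes, class counts and class shares under alternative settings, 6152 gave the same call, 578 no longer passed, 267 newly passed, 30 class counts moved and 6 turned. Those 6 were Fn1 (-0.36), Cybb (-0.0597) and Cd44 (-0.28) in brain microglia with all kept cells summed and Ms4a7 (0.0445), Negr1 (0.18) and Psd3 (0.88) in CD45.1 cells with a mixture per mouse. The type I interferon list turned in skull (adjusted p = 0.994) and in the interaction (0.749) without skull 5xFAD pool 2. Many of the 7033 values came from comparisons with 0 genes called, where few calls could change. There 465 of 465 in femur, 370 of 370 in skull, 338 of 338 in the interaction and 479 of 481 in chimera microglia were the same. Elsewhere it was 918 of 959 in brain, 985 of 1170 in chimera macrophages, 875 of 1211 for skull against femur, 506 of 675 in CD45.1 cells and 889 of 1007 after poly-IC.

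Counts of genes called moved as follows. Femur 5xFAD against WT (0) went to 1 with DESeq2, without both lane 2 skull pools and with femur samples alone, and to 2 with an assignment probability of at least 0.99 and with lane 1 alone; leave-one-out gave 0 to 0. Skull 5xFAD against WT (0) gave 0 to 1 (1 without skull WT pool 1). The interaction (0) gave 1 with DESeq2 and 0 to 1 leaving 1 out (1 without skull 5xFAD pool 1 and without skull WT pool 1). Skull against femur (156) gave 380 without a filter, 884 with DESeq2, 513 with Scrublet calls kept, 38 without a lane term, 4 at the 0.99 probability and 0 without both lane 2 skull pools. Leaving 1 out gave 0 to 752: 752, 16, 17 and 44 without femur 5xFAD 1 to 4, 68, 36 and 74 without femur WT 1 to 3, 27 and 7 without skull 5xFAD pools 1 and 2, and 5 and 0 without skull WT pools 1 and 2. The class counts (11) gave 4 to 86: 86, 38, 9 and 42 without femur 5xFAD 1 to 4 and 9, 4 and 5 without femur WT 1 to 3. Brain microglia (2175) gave 653 with all kept cells summed, 1362 with the replicate block and 909 to 1337 leaving 1 out: 1020 and 909 without 5xFAD 1 and 2, and 1320 and 1337 without WT 1 and 2. Chimera microglia (0) gave 4 without a filter, 9 with DESeq2, 5 with all cells and 0 to 1 leaving 1 out (1 without IFNAR1-KO 4). Chimera macrophages (244) gave 837 without a filter, 47 with the stricter cell filter, 808 with Scrublet calls kept, 5 with all cells, 46 at a Leiden resolution of 2, 950 with the highest doublet scores removed and 661 with the unnamed cluster. Leaving 1 out gave 89 (without IFNAR1-KO 3) to 474 (without WT 3), with 162 without IFNAR1-KO 1, 157 without IFNAR1-KO 2 and 106 without WT 4. CD45.1 against CD45.2 (398) gave 933 without a filter, 2975 with DESeq2, 0 with the highest doublet scores removed, 5887 with a mixture per mouse and 0 to 328 leaving 1 out (0 without WT 2 and without WT 3). The mixture per mouse called CD45.1 a component with a negative mean log2 ratio in the IFNAR1-KO chimeras and WT donor chimera 1. Poly-IC (14) gave 9 and 28 with pseudocounts of 0.1 and 10, 25 with a minimum of 50, 25 with quantile normalization, 5 with samples 1 to 3 and no block, 27 with a block by column number, 168 with DESeq2 and 39 with limma on the deposited values. Leaving 1 out gave 4 (without poly-IC 3) to 28 (without PBS 3), with 5 without PBS 2, poly-IC 1 or poly-IC 4.

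List tests are given as adjusted p. For the type I interferon list the estimated correlation and fry gave 0.756 and 0.87 in skull, 0.95 and 0.947 in the interaction, 0.731 and 0.317 in CD45.1 cells and 0.233 and 0.0932 after poly-IC. They gave 0.399 and 0.0181 in brain and 0.12 and 0.00367 in macrophages. In the chimera microglia comparison camera gave the list 0.0495 at a Leiden resolution of 2. It gave 3.71e-21 with all cells and 1.45e-23 with every cluster whose best type is microglia, sets that hold cells outside the microglia class. Leaving 1 out gave 9.98e-05 (without femur WT 3; 0.0296 without femur 5xFAD 1) to 0.938 in femur and 0.000327 to 0.994 in skull (0.0967 without skull WT pool 2). It gave 0.0587 to 0.898 for skull against femur, and 3.06e-06 to 0.749 for the interaction (0.052 without femur 5xFAD 4, 0.569 without femur WT 1, 0.234 and 0.0764 without skull WT pools 1 and 2). It gave 1.38e-20 to 8.26e-17 in brain, 0.000976 (without IFNAR1-KO 3; 0.00452 without IFNAR1-KO 2 and 0.00144 without WT 1) to 0.955 in chimera microglia, 6.27e-67 to 7.9e-40 in macrophages, 1.09e-08 to 0.000876 in CD45.1 cells and 4.43e-06 to 0.00073 after poly-IC. The disease-associated list in brain gave 0.206 with an estimated correlation, 0.00201 by fry and 5.74e-21 to 3.35e-20 leaving 1 out. The list of genes raised by poly-IC gave 0.0226 by fry in brain and 0.0338 (without 5xFAD 2) to 0.123, and 0.275 to 0.996 in femur, 0.492 to 0.9 in chimera microglia, 0.191 to 0.787 in macrophages and 0.518 to 0.818 in CD45.1 cells. The difference in the share called CD45.1 was -34.92 points by the tag ratio, -20.25 by a mixture per mouse and -5.46 by the planned mixture per lane, which leaving 1 out moved from -23.92 to 11.2 points, and class shares had 0 to 0 calls. The mixtures count the component of the higher ratio, whatever the sign of that ratio.

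Pairing by sample number was tested with a replicate block. By title the correlations of monocyte samples of 1 number were 0.0408, 0.00161 and 0.0137, against at most 0.0207 for other pairs, too low to treat them as paired. In the brain it was -0.0783, and in chimera macrophages the correlations were -0.282, -0.284, -0.195 and 0.115. The block gave 1362 genes in brain, 0 in chimera microglia, 277 in macrophages, and 17 (by title) or 27 (by column number) after poly-IC; the sample labels do not number the femur mice, which are numbered here in tag order, so no block was fitted there. The CD45 mixture per lane could give no gene comparison, since 1 mouse alone held both classes, so the tag ratio is reported. An assignment probability of at least 0.99 left at most 5 cells in each lane 2 sample and so kept lane 1 alone.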

Other observations

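None of the descriptions in the next 2 paragraphs was planned; they were made after the values were seen. Skull WT pool 2 held 631 CPM of Ttr, the thyroid hormone carrier of the choroid plexus, against at most 1.66 CPM in the other marrow samples, and 15.8 CPM of Ibsp, a bone matrix gene, against at most 1.01 CPM.

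In the WT donor chimeras, Trim12a and Trim12c, neighbouring antiviral genes, were lower in CD45.1 cells (0.00811-fold and 0.214-fold) beside the microglial genes. In monocytes Retnlg, a neutrophil granule gene, stood at 68.7 normalized counts after poly-IC against 0.974 after PBS (adjusted p = 0.173 in limma), while Mmp8 and Csf3r of the same list lay lower.

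Of the tests in this part, those of class mix and of donor sex were chosen only after the result was seen. The lower interferon list of the IFNAR1-KO chimeras was tested against another mix of macrophage classes. In each of the 4 donor-type classes fitted alone the median log2 fold change was -1.04 or lower, which a mix of these classes alone does not give. Border-associated macrophages, a part of the summed cells, were not fitted alone, so a fall within them was not shown. Sex of the donors could stand in place of their genotype, since 4 of 4 IFNAR1-KO chimeras exceeded every WT donor chimera in Y-linked transcripts of neutrophils, and the design cannot part them. The higher genes of the summed macrophages may reflect another mix of classes: 2.40% of the 167 genes called higher (4, all Y-linked) were also called higher in monocytes alone. That fit used fewer cells and called 50 genes in all. A low overlap can come from this too, so it cannot decide.

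Lists not called elsewhere in the text are given here with camera's adjusted p. In femur 5xFAD against WT these were type II interferon 0.132, MHC class II 0.978, disease-associated 0.533, homeostatic 0.533, inflammatory 0.908, immediate early 0.833, S phase 0.305, G2 and M phase 0.264, monocyte 0.264, stem cell 0.533, myeloid-biased 0.856, lymphoid 0.264, megakaryocyte 0.695, cholesterol 0.601, lysosome 0.132, ribosomal 0.264 and infiltrating macrophage 0.533. Erythroid cells gave 0.0547, platelets 0.533, dendritic cells 0.428, basophils 0.533 and stromal cells 0.305. There the disease-associated, homeostatic, inflammatory, monocyte and myeloid-biased lists had a negative mean beside an upward median and test, MHC class II and infiltrating macrophage lists a negative median and mean beside an upward test, and the basophil list a negative median beside an upward test. In the interaction the secondary granule list had a median of 0.73 and a test pointing down (0.204). In brain microglia the lists not called were S phase 0.602, G2 and M phase 0.373, primary granule 0.403, secondary granule 0.373, stem cell 0.884, myeloid-biased 0.373, lymphoid 0.299, erythroid 0.463, megakaryocyte 0.238, neutrophils 0.602, dendritic cells 0.86, neurons 0.81 and oligodendrocytes 0.584; astrocyte markers rose in 2 of 7 (3 over the list alone; 0.0138, and 0.484 with an estimated correlation). In chimera macrophages the monocyte list gave 0.724, infiltrating macrophages 0.246 and dendritic cells 0.0634. After poly-IC the lysosome list had a median of -0.05, a mean of 0.48 and an upward test (0.824), and the disease-associated list a median of -0.05, a mean of 0.11 and a downward test (0.789).

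Gm42418 took between 3.35% and 7.44% of the reads of each monocyte sample.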
